A study of Mus musculus with 4 samples.

How the data were processed

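Gene expression was measured in CGR8 cells, a line of mouse embryonic stem (ES) cells, on 4 Affymetrix whole-genome mouse arrays. Per the labels, 2 arrays held total RNA of cells kept with leukemia inhibitory factor (LIF) at 1000 U/ml and 2 held RNA of cells given medium without LIF, after 2 days. Per the labels' protocols the cells grew on gelatin in medium with serum replacement, RNA was extracted with Trizol, and biotinylated cRNA was made by in vitro transcription with T7 RNA polymerase. Arrays in each group carried the numbers 1 and 2 in the labels. The labels do not say that the arrays of a group came from separate cultures, so p-values of single genes measure only the spread between these arrays, which may be technical.

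The deposited values were MAS5 signal intensities on a linear scale, per the submitters' processing notes and the values themselves. The version of MAS5 was not given in the sources used here. MAS5 summarises the perfect-match and mismatch probes of a probe set within 1 array and scales each array to a common level. In the deposited table the mean signal without the lowest and highest 2% of probe sets was 499.8 to 499.9 on each array. Scaling of this kind sets the mean, which bright probe sets dominate, and does not align dim signals between arrays.

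The table held 45101 probe sets. Of these, 64 were control probe sets, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none there. Entrez identifiers of 34741 of the 34945 probe sets with 1 symbol matched the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. Only names were taken from that table. No genome build is given in the sources used here, and no coordinates are reported. Probe sets with several or no symbols and control probe sets were left out of the gene test. Each of 18193 genes was represented by its probe set with the highest mean log2 signal over the 4 arrays, and 9010 genes had more than 1 probe set. The only value at or below 0, of 1 probe set on 1 array, was raised to the smallest positive value before taking log2. Genes were tested when their mean log2 signal lay above the 30th percentile of probe sets without controls, which was 4.51 (a signal of 22.9), and 14445 genes passed.

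Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on log2 signals, with group as the only term, 2 residual degrees of freedom, two-sided p-values and Benjamini-Hochberg adjustment over the tested genes at a threshold of 0.05. Log2 changes are without LIF minus with LIF, SE is the moderated standard error, and means ± SD are of linear signals. As a description by size, genes were counted whose mean log2 signal differed by at least 1 (2-fold) and whose 2 arrays without LIF both lay beyond the 2 arrays with LIF. Chance places 2 groups of 2 apart for 33% of genes. The 28 gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists, and with an estimated correlation and the rotation test fry as alternatives. At the preset correlation camera compares members with the other tested genes. Its p-values then rest on the spread over genes at an assumed correlation, not on replication of arrays. With an estimated correlation camera uses the residual degrees of freedom, which are 2 here and 1 with the replicate number in the fit. A call is then hard to reach with 4 arrays, whatever the correlation. List medians were also set against 10000 random lists drawn from 20 bins of mean signal. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

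The text names 10 genes with the largest rises and 10 with the largest falls among genes that passed the test, whose groups did not overlap and whose names are not those of clones or predicted transcripts. Where fewer than 10 passed, genes with the smallest unadjusted p fill the number and are said not to pass. It also names up to 4 members of a list, those with the smallest p, and, whatever their values, Socs3, Klf4, Klf5, Tfcp2l1, Esrrb, Nanog, Tbx3, Zfp42, Pou5f1, Sox2, Fgf5, Otx2, Dnmt3b, T, Gata6, Gata4, Sox1, Cdx2, Actb and Gapdh. T and Gapdh had no probe set with a single symbol here, and Cdx2 lay below the filter, so these 3 were not tested.

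The alternatives were no filter, a filter at the 50th percentile, a pseudocount at the 20th percentile of signals (14.3), quantile normalization, a common median per array, eBayes without the trend or with robust estimation, the mean of a gene's probe sets, the brightest plain probe set, the replicate number as a block, leaving out each array, an adjusted p of 0.1, and a test of every probe set. The block combined with quantile normalization, and the 2-fold count within each number, were added after the data had been seen.

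The fit was tested on simulated data with the levels, spreads and differences between numbers of the 14445 genes, in 10 runs with 200 changed genes each. With each gene's own spread estimate, which has 1 degree of freedom and is very uneven between genes, the fit without the block found 14.9% of 8-fold, 3.49% of 4-fold and 0 of 675 2-fold changes, and the fit with the block found 0 changes of any size. A second setting, with limma's moderated spread, was added after that outcome had been seen, and both are given here. There the fit without the block found 65.5% of 8-fold, 42.9% of 4-fold and 0.889% of 2-fold changes with 0 false calls among 718, and the fit with the block found 87.8%, 81.1% and 60.9%, with 140 false calls among 1668 (8.39%). That share of false calls lies above the threshold of 0.05. The simulated number differences and spreads were taken from the fit with the block, which keeps 1 residual degree of freedom. Its gain over the other fit was therefore partly built in. Mean estimates of the 2-fold, 4-fold and 8-fold changes were 1.00, 2.01 and 2.99 on the log2 scale. The number of arrays limits the precision of every comparison.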

Results

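The study addressed gene expression that depends on LIF signalling in mouse ES cells. LIF is a cytokine that acts through the receptor subunits Lifr and Il6st on the kinase Jak1 and the transcription factor Stat3, and it is added to keep ES cells undifferentiated. Transcripts were measured on 4 arrays, 2 of CGR8 ES cells with LIF at 1000 U/ml and 2 of cells without LIF for 2 days. Median signals were 69.9 and 59.6 with LIF and 95.5 and 65.5 without LIF. Across the 14445 tested genes the log2 signals of the arrays with LIF correlated at r = 0.962 and those without LIF at r = 0.948. Arrays of the same number in different groups correlated at 0.952 and 0.953 and the other pairs at 0.946 and 0.932, and genes are not independent replicates. The most probe sets with equal values on any pair of arrays was 127 of 45101, so no array repeated another.

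Several control probe sets differed between the arrays numbered 1 and those numbered 2 in each group. The 18S ribosomal RNA signal was 462 with LIF and 451 without LIF on the arrays numbered 1, and 5150.4 and 2990.4 on those numbered 2. The poly-A control dap, a bacterial RNA added to samples before labelling, read 3175 and 1692.5 on the arrays numbered 1 and 849 and 795 on those numbered 2. The ratio of 3' to 5' Actb signals, a measure of RNA integrity, was 1.32 and 1.44 on the arrays numbered 1 and 1.83 and 1.77 on those numbered 2. The same ratio for Gapdh did not differ in this way, at 0.784 and 0.793 on the arrays numbered 1 and 0.785 and 0.783 on those numbered 2, and the hybridization control bioB read 1.01 and 1.10 times as high on the arrays numbered 2. Another hybridization control, cre, read 1.20 times as high on the array numbered 2 with LIF and 1.34 times without LIF. This split by number was recognised only after the values had been seen. Counts with the number as a block, and changes within each number, therefore stand beside the main results.

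Transcripts of the LIF response and of the naive ES cell state were lower without LIF. Bcl3, a nuclear cofactor of NF-kappaB, fell by 4.90 on the log2 scale (29.8-fold; SE 0.29; adjusted p = 0.0046), from a signal of 1202 ± 159 to 40.2 ± 1.41 (SD, n = 2). Socs3, the feedback inhibitor of JAK and STAT signalling, fell by 4.16 (17.8-fold; SE 0.24; adjusted p = 0.0046), from 5512 ± 969 to 311 ± 69.7 (SD, n = 2), and its 3 probe sets were all lower. With the brightest plain probe set in its place Socs3 had a log2 change of -3.74 (adjusted p = 0.057). Klf4, a transcription factor of the naive state, fell by 3.84 (14.3-fold; SE 0.28; adjusted p = 0.010), from 6666 ± 1886 to 466 ± 132 (SD, n = 2). In the other direction, Pou3f1, a POU factor of the epiblast, rose by 3.61 (12.2-fold; SE 0.35; adjusted p = 0.026), and the kinase Pim2 rose by 3.50 (11.3-fold; SE 0.33; adjusted p = 0.026).

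Altogether 21 genes passed the limma test at an adjusted p of 0.05, 7 of them higher and 14 lower without LIF, and 1573 of 14445 had an unadjusted p of 0.05 or less. A split of the same arrays by number gave 1 and 1211 such genes, and the remaining split into 2 and 2 gave 0 and 52. The other large falls were of Mymx, a micropeptide of myoblast fusion (log2 change -4.14), Ly6g6e (-3.02), Pcolce, an enhancer of procollagen processing (-2.91), Msc (-2.56), Lrrc34 (-2.45), the nuclear receptor Esrrb (-2.27) and Tfap2c (-2.16). The other rises were of Has2, a hyaluronan synthase (3.27), Cthrc1 (3.12), the carbonic anhydrase Car4 (2.51), Fam171b (2.02) and Cachd1 (1.97). Fgfbp1, Ptpn13 and Ccdc136 filled the places up to 10 with log2 changes of 2.25, 2.19 and 1.94 and did not pass (adjusted p = 0.054 for each), though each passed with the replicate number as a block. For all 21 genes the arrays of the groups did not overlap, which held for 42.5% of tested genes against 33% by chance. With the replicate number as a block 975 genes passed, 596 higher and 379 lower, including all 21, while eBayes without the mean-variance trend called 0 (1589 at an unadjusted p of 0.05 or less), quantile normalization 10, and a common median 4 higher and 14 lower (22.2% higher against 33%). There were 39 calls when array 1 with LIF was left out, 7 when array 2 with LIF was left out, 303 when array 1 without LIF was left out and 496 when array 2 without LIF was left out. Bcl3, Socs3, Klf4, Mymx, Pcolce, Pou3f1 and Pim2 passed with each array left out, and the other 14 did not pass when array 2 with LIF was left out. Msc and Fam171b were among the genes that also did not pass when array 1 with LIF was left out (log2 changes of -2.67 and 2.04).

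**Figure D1:**
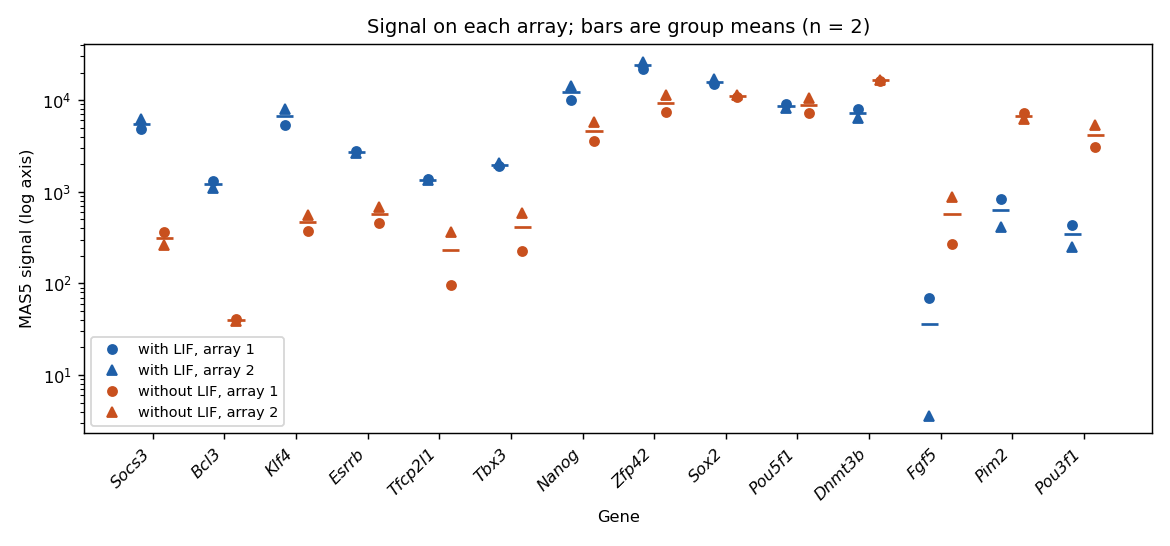
MAS5 signal (log axis) of 14 genes on each of the 4 arrays, with LIF in blue and without LIF in orange, circles for the arrays numbered 1, triangles for those numbered 2 and bars for group means (n = 2). Socs3 lies between 4827 and 6198 with LIF and between 261 and 360.0 without LIF, whereas the groups overlap for Pou5f1.

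The fixed list of LIF and STAT3 target genes was lower without LIF as a group. Of its 25 tested members 0 rose and 3 fell over all genes tested (Socs3, Bcl3 and Klf4), and 16 fell when adjusted over the list alone. With the block 15 fell and 1 rose. The list median was -1.26, with -1.24 within the arrays numbered 1 and -1.01 within those numbered 2 (camera, adjusted p = 4.8e-18). The adjusted p was 0.28 with an estimated correlation. Pim3, a kinase and member of the list, had a log2 change of -1.50 (adjusted p = 0.054) and passed with the block. Among the 17 tested receptor pathway components 0 passed, and 2 fell when adjusted over the list alone, the receptor subunit Lifr by 1.70 and Stat3 by 1.53. Pias3 and Grb2 read 1.04 and -0.38. With the block 1 component rose, Pias3, and 2 fell. The median of that list was 0.12 (0.02 with quantile normalization), its mean -0.06 and its test pointed down (adjusted p = 0.18), and the list passed when array 2 with LIF was left out (median -0.22, adjusted p = 0.048) and when array 1 without LIF was left out (-0.15, 0.039). Dim single probe sets of Pim3 and Stat3 read the opposite way.

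The naive pluripotency list had a median of -1.39 over 24 tested members (camera, adjusted p = 7.4e-24), with -1.56 and -1.23 within the arrays numbered 1 and 2. The adjusted p was 0.45 with an estimated correlation. Klf4, Jam2 and Esrrb fell over all genes tested, 17 members fell adjusted over the list alone, and with the block 18 fell and 1 rose. Prdm14, a repressor in naive and germ cells, read -2.02 (adjusted p = 0.054) and passed with the block. Tfcp2l1 (-2.86), Tbx3 (-2.43), Klf5 (-1.99), Nanog (-1.41) and Zfp42 (-1.38) did not pass over all genes (adjusted p = 0.12, 0.084, 0.12, 0.12 and 0.084), and each passed with the block. Dim single probe sets of Klf5 and Tfcp2l1 read the opposite way. Klf4, Klf5, Gbx2 and Tfcp2l1 are also on the list of LIF and STAT3 targets, and Tbx3 is also on that of BMP targets. The calls of these lists are therefore not independent. Esrrb and Jam2 did not pass when array 2 with LIF was left out (adjusted p = 0.15 and 0.16) or with quantile normalization (0.079 and 0.078).

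General pluripotency genes differed less between the groups. Pou5f1, which encodes Oct4, had signals of 8640.2 ± 558 with LIF and 8922 ± 2418 without LIF (SD, n = 2; log2 change 0.02, SE 0.22, adjusted p = 0.99; -0.12 with a common median), and Sox2 had a log2 change of -0.52 (SE 0.16, adjusted p = 0.31, and 0.018 with the block). The list of 21 tested members had a median of -0.25 (camera, adjusted p = 0.0011), with -0.40 and -0.09 within the numbers, and the adjusted p was 0.46 with an estimated correlation. The median was -0.14 when array 1 without LIF was left out and -0.38 when array 2 without LIF was left out. Over all genes 0 members passed. Adjusted over the list alone Lin28a, an RNA-binding protein, rose by 0.87, and Mybl2 and Tdgf1 fell by 1.04 and 1.48. With the block 1 rose and 4 fell.

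Formative and primed epiblast genes were higher without LIF, with a list median of 1.20 over 25 members and 1.02 and 1.37 within the numbers (camera, adjusted p = 9.3e-10). The adjusted p was 0.45 with an estimated correlation. The median was 0.73 when array 2 with LIF was left out and 0.76 when array 1 without LIF was left out. Pim2 and Pou3f1 rose over all genes tested. Adjusted over the list alone 14 rose and 1 fell, and with the block 16 rose and 1 fell. The de novo DNA methyltransferase Dnmt3b read 7167 ± 1142 with LIF and 16401 ± 296 without LIF (SD, n = 2; log2 change 1.20, adjusted p = 0.065), and Fgf15 had a log2 change of 2.29 (adjusted p = 0.071). Both passed with the block. Fgf5, the usual epiblast marker, had a log2 change of 4.96 with an SE of 1.29 (adjusted p = 0.21, and 0.015 with the block), 1.99 within the arrays numbered 1 and 7.94 within those numbered 2. The size is uncertain, since Fgf5 read 68.8 and 3.6 with LIF and the filter lay at 22.9. Otx2 had a log2 change of 0.32 (adjusted p = 0.73), and of -0.06 when array 2 with LIF was left out.

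**Figure D2:**
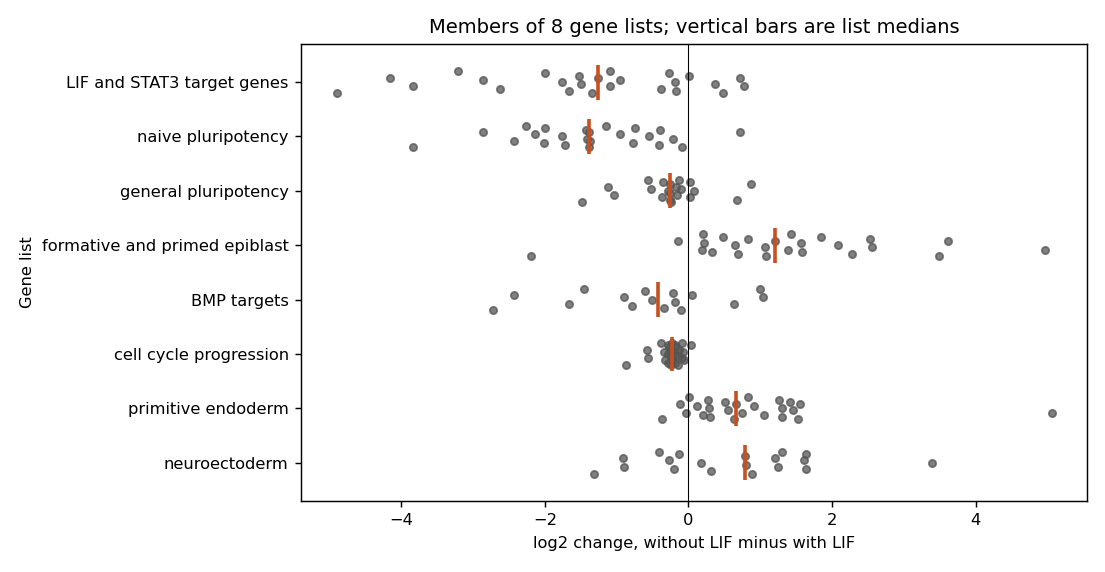
Log2 change (without LIF minus with LIF, horizontal axis) of each tested member of 8 gene lists (rows), with grey points for genes, spread vertically only for legibility, and orange bars for list medians. The medians of the LIF target, naive and formative lists lie at -1.26, -1.39 and 1.20, and that of general pluripotency at -0.25.

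Of the signalling and chromatin lists, that of BMP targets passed. It had a median of -0.43 over 16 members (-0.67 with quantile normalization), -0.31 and -0.59 within the numbers (camera, adjusted p = 7.2e-04, and an adjusted p of 0.45 with an estimated correlation). Bmp4 (-2.73), Tbx3 (-2.43), Id3 (-1.66) and Smad7 (-0.90) fell adjusted over the list alone, with 0 over all genes, and with the block 1 member rose and 6 fell. The FGF and ERK feedback list did not pass in camera (adjusted p = 0.25) but passed fry's test of change in either direction (0.0044), and adjusted over it alone Fgfr2 and Dusp4 rose by 1.25 and 1.09 while Epha4 and Etv4 fell by 1.44 and 2.19. With the block 5 rose and 4 fell. Of the NODAL and activin targets (adjusted p = 0.25; median 0.03, mean -0.36, test down) 3 rose and 4 fell adjusted over the list alone, among them Skil (1.11), Inhbb (-4.35, with a signal of 15.4, below the filter, on array 1 without LIF), Tdgf1 (-1.48) and Lefty2 (-1.34), and with the block 3 rose and 5 fell. The WNT list (adjusted p = 0.83; median 0.33, or 0.01 with quantile normalization, mean 0.17, test down) held Lef1, which rose by 2.54, and Bmp4, both adjusted over the list alone. Notum and Ccnd1 read -0.81 and 0.47. With the block 2 rose and 2 fell, Notum among them. For the list of DNA methylation and chromatin genes (median -0.11, adjusted p = 0.054, and 0.016 with the block) the adjusted p was 0.56 with an estimated correlation and 0.65 with both. Of its members 2 rose and 4 fell adjusted over the list alone, and 2 and 6 with the block. Among them were Dnmt3b (1.20), Prdm14 (-2.02), the Polycomb subunit Eed (-0.82, with a dim probe set the opposite way) and the demethylase Kdm3a, with mean signals of 6147 and 3099. That list passed when array 2 with LIF or array 2 without LIF was left out (medians of -0.23 and -0.10). It also passed with a common median (median -0.25, adjusted p = 0.049) and with plain probe sets (-0.21, 0.027).

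Lineage markers showed no call over all genes tested apart from Tfap2c, which is also on the trophoblast list. The primitive endoderm list had a median of 0.66 over 25 members (camera, adjusted p = 0.0080, and an adjusted p of 0.63 with an estimated correlation). Adjusted over the list alone Lrp2 and Serpinh1 rose by 1.52 and 0.91, and with the block 9 members rose. The list depended on single arrays, since its median was 0.08 when array 1 with LIF was left out (adjusted p = 0.38), -0.20 when array 2 without LIF was left out (0.31), 1.23 when array 2 with LIF was left out and 1.62 when array 1 without LIF was left out, and it did not pass without the trend (0.069). Most of its members were higher on the arrays numbered 2 than on those numbered 1, 21 of 25 in both groups, while Plat was lower in both. The list medians of that difference were 1.11 with LIF and 1.92 without LIF, and the medians of change were 0.30 and 0.84 within the numbers. Gata6 read 124.5 and 445 with LIF and 132 and 611 without LIF on arrays 1 and 2 (log2 change 0.27, adjusted p = 0.93), and Gata4 had a log2 change of 0.31 (adjusted p = 0.89). Both changed sign when array 1 with LIF was left out (-0.65 for Gata6 and -0.25 for Gata4) and when array 2 without LIF was left out (-0.84 and -0.32). Ttr and Plat read 5.06 and 1.55 (adjusted p = 0.24 and 0.41, and 4.3e-04 and 0.0078 with the block), and the mean Ttr signal with LIF, 17.1, lay below the filter, so the size of its change is uncertain. These values are for the brightest probe set of Ttr, and its others had smaller log2 changes of 2.28, 3.14 and 3.99. The probe set at 2.28 read 7.3 with LIF and 8.1 without LIF on the arrays numbered 1, and 20.6 and 437.7 on those numbered 2.

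**Figure D3:**
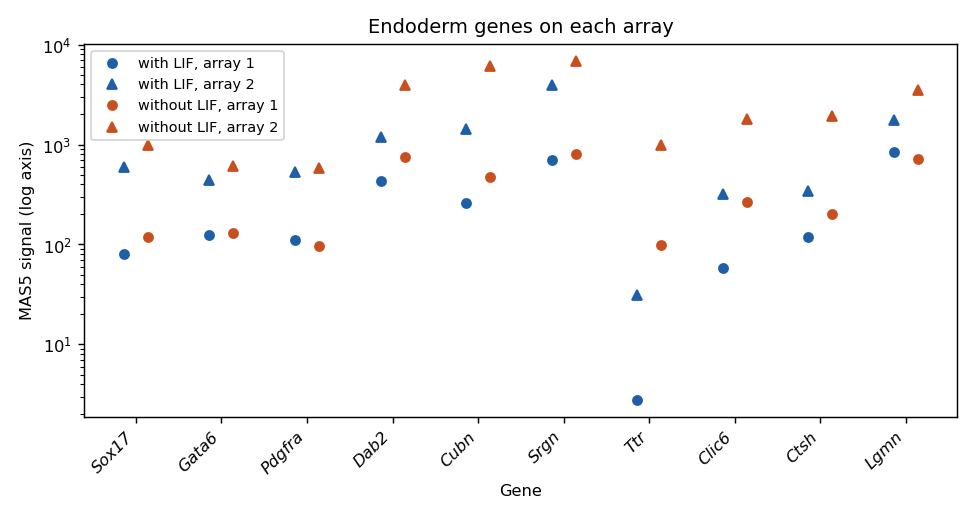
MAS5 signal (log axis) of 10 endoderm genes, chosen after their values were seen, on each of the 4 arrays, with LIF in blue, without LIF in orange, circles for the arrays numbered 1 and triangles for those numbered 2. Each gene is higher on the array numbered 2 of its group, as for Cubn at 262 and 1447 with LIF and 477 and 6045 without LIF.

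The lists of primitive streak and mesoderm (20 members, median 0.50, adjusted p = 0.18), neuroectoderm (19, 0.78, 0.47), trophoblast (16, 0.22, 0.40), germ line (23, 0.32, 0.16), 2-cell-like state (9, -0.37, 0.38) and blood and endothelium (14, 0.37, 0.53) did not pass in camera. Only 9 of the 22 fixed members of the 2-cell-like list had a probe set with a single symbol here. Zscan4c, Zscan4d, Zscan4f and Dux were among those without one, so that state was hardly tested. In fry's test of change in either direction the primitive streak and trophoblast lists passed (adjusted p = 0.034 and 0.040). With the block 2 members rose and 1 fell of primitive streak and mesoderm, 7 and 3 of neuroectoderm, 4 and 1 of trophoblast, 4 and 1 of germ line, 0 and 0 of the 2-cell-like state and 0 and 1 of blood and endothelium. With quantile normalization the medians of primitive streak, neuroectoderm, trophoblast and blood were smaller, at 0.30, 0.45, 0.03 and 0.11. Neuroectoderm genes were lower on the arrays numbered 2, by a median of 0.63 with LIF and 1.28 without LIF on the log2 scale, and their list passed when array 1 with LIF was left out (median 0.95, adjusted p = 0.015) and when array 2 without LIF was left out (1.14, 0.0017). Its median was 0.22 when array 2 with LIF was left out (0.70) and 0.11 when array 1 without LIF was left out (0.42). The germ line list passed when array 2 with LIF was left out (median 0.45, 0.048) and when array 1 without LIF was left out (0.50, 3.2e-04), and its median was 0.14 when array 2 without LIF was left out (0.62). Sox1 had a log2 change of 1.31 (adjusted p = 0.46, and 0.0066 with the block). It was 2.15 when array 2 without LIF was left out (0.0040) and 0.47 when array 1 without LIF was left out (0.73). Adjusted over their lists alone, Fgf8 rose by 4.30 from a signal of 5.5 ± 1.98 (SD, n = 2) near the floor, Bmp4 fell, Stmn2 fell by 1.32, Tfap2c fell, Kitl and Sycp2 rose by 1.65 and 1.73, and Kit fell by 1.10. Fibroblast and smooth muscle genes passed (median 0.62, or 0.39 with quantile normalization, 0.49 and 0.91 within the numbers, adjusted p = 0.012, and an adjusted p of 0.55 with an estimated correlation). Adjusted over that list alone 4 rose and 1 fell (5 and 1 with the block), among them Ccn2 (1.67), Col5a2 (1.17) and Dcn (1.43, with a dim probe set the opposite way) up and Vim (-0.86) down. That list did not pass when array 2 with LIF was left out (median 0.28, adjusted p = 0.27), when array 1 without LIF was left out (0.40, 0.079) or with the mean of all probe sets (0.12). Epithelial and mesenchymal adhesion genes passed as well (median 0.39, 0.31 and 0.50 within the numbers, adjusted p = 0.0036, and an adjusted p of 0.45 with an estimated correlation), with 0 members past the test and Esrp1, a splicing factor of epithelia, at 1.79. With the block 3 members rose, Esrp1 among them. The median of the list was 0.73 when array 1 with LIF was left out.

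Cell cycle progression genes were slightly lower, with 28 of 29 log2 changes negative, a median of -0.23 (camera, adjusted p = 5.9e-07, and an adjusted p of 0.37 with an estimated correlation) and medians of -0.27 and -0.20 within the numbers. Over all genes and over the list alone 0 members passed, with the block 2 fell (Ccne1 and Tk1), and Ccne1, Tk1, Rrm2 and Cdk2 read -0.87, -0.58, -0.39 and -0.35, with a dim probe set of Cdk2 the opposite way. The list of cell cycle inhibitors and D cyclins passed (median 0.30, 0.56 and 0.29 within the numbers, adjusted p = 0.044, and an adjusted p of 0.45 with an estimated correlation). Over all genes 0 members passed, and adjusted over the list alone 5 rose and 2 fell (6 and 2 with the block), among them the growth arrest gene Gadd45g (2.62), the CDK inhibitors Cdkn1a (1.28) and Cdkn1c (1.44) and Gadd45b (-1.58). The list passed fry's test of change in either direction (adjusted p = 0.018). In camera it did not pass when array 1 with LIF was left out (0.056), when array 2 without LIF was left out (0.078), without the trend (0.11) or with plain probe sets (0.053). The p53 and apoptosis list passed (median 0.44, 0.26 and 0.71 within the numbers, adjusted p = 0.0036, and an adjusted p of 0.46 with an estimated correlation) with 0 members past the test (4 rose with the block, Pmaip1 among them) and Pmaip1 at 1.32, but not when array 2 without LIF was left out (median 0.19, adjusted p = 0.22).

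Imprinted genes had a median of 0.42, 0.52 and 0.46 within the numbers (camera, adjusted p = 0.013, and an adjusted p of 0.45 with an estimated correlation). Adjusted over the list alone Meg3, Grb10 and Sgce rose by 1.39, 1.52 and 1.33, with the block 6 members rose, and the 11 probe sets of Meg3 were all higher. The median was 0.86 when array 1 with LIF was left out and 0.82 when array 2 without LIF was left out. The list did not pass when array 2 with LIF was left out (median 0.10, adjusted p = 0.19), when array 1 without LIF was left out (0.10, 0.062), without the trend (0.071), with the mean of all probe sets (0.17) or with plain probe sets (0.051). Oxidative phosphorylation genes had a median of -0.10, -0.11 and -0.07 within the numbers (adjusted p = 0.018, and an adjusted p of 0.63 with an estimated correlation) and no call with quantile normalization (-0.02, adjusted p = 0.54), when array 2 with LIF was left out (median 0.01, adjusted p = 0.27) or when array 1 without LIF was left out (0.02, 0.54). The median was -0.17 with either of the other arrays left out. Among random lists of like signal it lay at percentile 28.3, whereas the medians of the other 12 lists that passed lay at 0.02 or below or at 99.0 or above. Of lists that did not pass, neuroectoderm and germ line also lay above 99.0, and the 2-cell-like state and FGF and ERK feedback lay at 0.18 and 0.37. Glycolysis (median -0.16, adjusted p = 0.056, and 0.031 with the block), sterol synthesis (-0.15, 0.33) and stress response (0.09, 0.54) did not pass. With the block and an estimated correlation the adjusted p of glycolysis was 0.61. With the block 2 members rose and 1 fell of glycolysis, 4 and 1 of stress response, 1 and 1 of common reference genes, 0 and 1 of oxidative phosphorylation and 0 and 0 of sterol synthesis. Glycolysis passed when array 2 with LIF or array 2 without LIF was left out (medians of -0.09 and -0.16). It also passed with a common median (median -0.30, adjusted p = 0.044) and with no filter (-0.16, 0.043). Sterol synthesis passed when array 1 without LIF was left out (0.032), and stress response passed upward when array 1 without LIF was left out (median 0.48, 9.3e-06) and downward when array 2 without LIF was left out (-0.15, 0.020). Common reference genes did not pass as a list (-0.08, adjusted p = 0.15) but did when array 2 without LIF was left out (-0.25, 0.020). Actb, a cytoskeletal gene, had a log2 change of 0.02 (adjusted p = 0.98; -0.12 with a common median), and Tfrc, the transferrin receptor, fell by 0.82 adjusted over that list alone.

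By size, 1063 genes were at least 2-fold higher and 306 at least 2-fold lower without LIF with groups that did not overlap, so that 77.6% were higher. The other 2 ways to split the arrays into 2 and 2 gave 918 genes (arrays numbered 1 against 2) and 415. Within each number 549 genes were 2-fold higher and 182 were 2-fold lower on both comparisons, and 157 went opposite ways. A lone array makes overlap less likely, and there were 1435 higher and 476 lower when array 1 with LIF was left out, 1325 and 397 when array 2 with LIF was left out, 1188 and 608 when array 1 without LIF was left out, and 1940 and 575 when array 2 without LIF was left out. The excess of higher genes lay among dim genes, with 552 higher and 89 lower in the dimmest 2889 genes and 23 higher and 36 lower in the brightest 2889. With quantile normalization 637 were higher and 451 lower (58.5% higher), and with a common median per array 774 and 401 (65.9%). The median log2 change of all tested genes was 0.09 on the deposited scale and -0.05 with a common median, a shift of 0.14. Relative to it, the medians of 3 lists changed sign, those of receptor pathway components (-0.02), NODAL and activin targets (-0.11) and stress response (-0.05), and the medians of the other 25 did not. Of lists that passed, the medians of general pluripotency, cell cycle progression and oxidative phosphorylation were larger in size with a common median (-0.39, -0.37 and -0.24). Those of adhesion, cell cycle inhibitors and imprinted genes were smaller (0.25, 0.16 and 0.28).

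**Figure D4:**
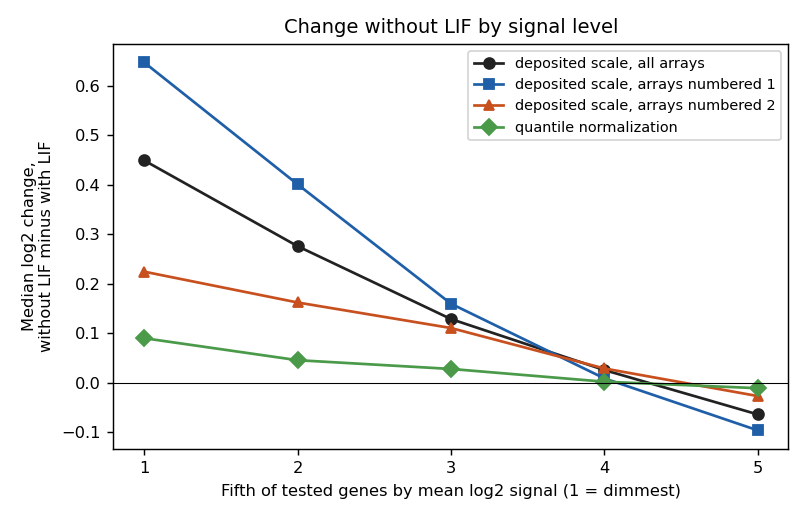
Median log2 change (without LIF minus with LIF, vertical axis) in 5 equal groups of the tested genes by mean log2 signal (horizontal axis, 1 is the dimmest; 2889 genes each), on the deposited scale over all arrays, within the arrays numbered 1, within those numbered 2, and after quantile normalization. The median falls from 0.45 to -0.06 on the deposited scale and from 0.09 to -0.01 after quantile normalization.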

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

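The probe sets described here were chosen after the data had been seen, as those with the smallest p in each direction among probe sets whose annotation gives no symbol here, which the gene test leaves out. The probe set 1452004_at had a log2 change of 2.45 (signals of 576 and 362 with LIF, 2333 and 2661 without LIF; adjusted p = 0.16 by limma, and 1.1e-05 with the replicate number as a block). The probe set 1431094_at had a log2 change of 1.48 (992 and 689 with LIF, 2430.5 and 2199 without LIF; adjusted p = 0.26, and 9.0e-05 with the block). In the other direction 1416715_at and 1437534_at had log2 changes of -3.02 and -2.66 (adjusted p = 0.15 and 0.20). Of the 5121 probe sets with no symbol or several above the filter, 409 were at least 2-fold higher without LIF with groups that did not overlap and 93 were at least 2-fold lower, on the deposited scale on which dim genes were also higher. In a limma test of each of 31526 probe sets by itself 0 passed, with 2152 at an unadjusted p of 0.05 or less and a smallest adjusted p of 0.086, and 1566 passed with the block. No explanation was tested for these probe sets.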

How the results depend on the processing

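The block with quantile normalization and the 2-fold count within each number were chosen after the data had been seen. The counts of changed genes moved with most settings, and the cause was not tested except where named. Against 21 (7 higher, 14 lower), limma called 41 (19, 22) with a filter at the 50th percentile, where fewer genes are tested, 40 (18, 22) with the pseudocount, 10 (3, 7) with quantile normalization, 52 (26, 26) with robust eBayes, 12 (3, 9) with the mean of all probe sets, 140 (73, 67) at an adjusted p of 0.1, 0 (0, 0) for every probe set by itself with 2152 at an unadjusted p of 0.05 or less, and 0 (0, 0) without the trend, with 1589 at that p. A common median gave 4 higher and 14 lower. The replicate block gave 975 (596, 379), and the block with quantile normalization 720 (404, 316). Differences between the numbers in the 2 groups correlated across genes at r = 0.29, but labels give only a shared number and there are 2 pairs, so this is a hint from the data. With the block all 21 genes passed, the lists of DNA methylation and chromatin and of glycolysis were also called, and the other list calls did not change. With the block and an estimated correlation no list passed (smallest adjusted p 0.58), at 1 residual degree of freedom, where a call is hard to reach. Leaving out 1 array gave 7 to 496 changed genes, 2 to 256 higher and 5 to 240 lower, with 1 array in a group assumed to vary like the other group's. All 21 kept their direction in every setting, and 7 to 21 of them passed when an array was left out.

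Against 1369 genes with 2-fold change (1063 higher, 306 lower), no filter gave 2522 (1923, 599), the filter at the 50th percentile 703 (488 higher), quantile normalization 637 higher, and the count within each number 731 (549, 182), which asks for 2 comparisons. Leaving out 1 array gave 1722 to 2515 (1188 to 1940 higher, 397 to 608 lower), where a lone array makes overlap less likely. The lists of LIF and STAT3 targets, naive pluripotency, general pluripotency and formative genes kept their direction and call in each camera setting with the preset correlation, with medians of -1.40 to -0.93, -1.70 to -1.10, -0.39 to -0.14 and 0.73 to 1.40. With an estimated correlation their medians of -1.26, -1.39, -0.25 and 1.20 had adjusted p of 0.28, 0.45, 0.46 and 0.45, and none of the 28 lists passed (smallest 0.28), against 13 with the preset one. That loss also reflects the 2 residual degrees of freedom used there, and not correlation alone. LIF and STAT3 targets had an estimated correlation of -0.03, below the preset 0.01, yet their unadjusted p in camera rose from 3.4e-19 to 0.0099. The naive, general and formative lists had estimated correlations of 0.54, 0.13 and 0.22, all above the preset one. For these lists the preset correlation may be too low, and their p-values at that setting too small. In fry, which compares a list with no other genes, 0 lists passed the test of a common direction and 5 that of change in either (LIF and STAT3 targets, FGF and ERK feedback, cell cycle inhibitors, primitive streak and trophoblast). LIF targets and the naive, general and formative lists had adjusted p of 0.061, 0.18, 0.36 and 0.24 for direction and 0.0041, 0.082, 0.058 and 0.058 for either. The 2 lists whose test turned the other way, with a call before or after, did so when array 2 without LIF was left out, with the primitive endoderm list at -0.20 and the stress response list at -0.15 (adjusted p = 0.31 and 0.020), in ranges of -0.20 to 1.62 and -0.15 to 0.48 when 1 array was left out. The medians of oxidative phosphorylation and of several lists that did not pass also changed sign when an array was left out. Signal over background limits dim genes, and MAS5 detection calls were not used here. With the block 16 rose and 7 fell of the dimmest 2889 genes, and 86 rose and 130 fell of the brightest.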

Other observations

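Of the tests of explanations in this part, those of the control RNAs, of the share of rises under quantile normalization, of the receptor genes above the filter, of the 2 pluripotency lists and of the naive list under quantile normalization were chosen after the result was seen. The genes of this paragraph and the next were also chosen after their values were seen, and their directions held under quantile normalization and a common median. Apart from Car4, the genes of this paragraph did not pass at an adjusted p of 0.05 without the replicate number as a block. The Notch ligand Dll1 had a log2 change of 2.72 (adjusted p = 9.6e-04 with the block and 0.077 without it), the ephrin Efnb2 2.51 (4.4e-04 and 0.060) and the GDNF receptor Gfra1 2.56 (0.0011 and 0.069). Cyp26a1, which degrades retinoic acid, had 2.10 (5.0e-04 and 0.45, with groups that overlapped) and Crabp2, which binds it, 1.21 (0.0028 and 0.42). Wt1 and Prom1 had log2 changes of 2.95 and 2.56 (1.3e-04 and 1.5e-04 with the block, 0.054 for both without it). The carbonic anhydrases Car2 and Car3 had log2 changes of 1.11 and 2.36 (5.6e-04 and 3.8e-04 with the block, 0.072 and 0.19 without it), beside 2.51 for Car4. Khdc3, an oocyte and ES cell gene, and Gjb5 were lower, by log2 changes of -2.91 and -2.27 (8.4e-06 and 5.2e-04 with the block, 0.054 and 0.055 without it).

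Pim1 and Pim3, kinases induced by STAT3, had log2 changes of -1.26 and -1.50, and Pim2 had 3.50 (adjusted p = 0.0012, 2.9e-04 and 6.6e-06 with the block, 0.077, 0.054 and 0.026 without it). Lefty1 and Lefty2 read 0.65 and -1.34 (0.018 and 0.0090 with the block, 0.26 and 0.18 without it). Id2 read 1.05 with groups that overlapped, Id3 -1.66 and Id1 -0.61 (0.0077, 0.0076 and 0.18 with the block, 0.56, 0.14 and 0.55 without it). Differences between family members were not tested. The transferrin receptor control probe sets, which the gene test leaves out, had log2 changes of -1.26, -1.38 and -1.69 for their 3 parts, beside -0.82 for the brightest probe set of Tfrc. Its other probe sets had -1.20 and -1.41.

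The first pattern weighed is the lower level of naive genes without LIF. As the whole cause, the tables argue against ES cells giving way to cells without general pluripotency genes. That would lower the general list as much. The naive median lay below the general one (difference -1.13 on the log2 scale, 24 and 21 genes, 0 shared, two-sided permutation p = 3.4e-04 over genes, which are not independent). A larger share of epiblast-like cells that keep general pluripotency genes is not excluded by this comparison, and formative genes were higher (median 1.20). The tables also argue against an offset of dim signals as the whole cause. Without LIF the dimmest 2889 genes were higher (median 0.45), and random lists of like signal to the naive list had a median of -0.002. The naive median was -1.32 with quantile normalization, but with an offset upward that test had little room to turn out otherwise. A loss of naive expression within cells that keep Pou5f1 may account for the pattern, as a hypothesis. It cannot be told apart from a larger share of epiblast-like cells, since single cells were not measured here.

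The second pattern is that arrays numbered 2 differed from arrays numbered 1 in both conditions. An offset of dim signals is argued against as the whole cause, because the differences between numbers still correlated across genes at r = 0.30 with quantile normalization. A batch of RNA preparation or labelling is a candidate explanation, as 4 of the 4 poly-A control RNAs were lower on the arrays numbered 2 in both groups. The 4 were read on the same arrays and are not independent. As RNAs added to the samples, they do not bear on steps before the addition. A larger share of endoderm-like cells in the cultures numbered 2 is another, since 29 endoderm secretory genes, listed before their values were seen and with 0 on the fixed lists, were higher on the arrays numbered 2 by a median of 0.62 with LIF and 0.92 without LIF over 26 tested genes, above all of 10000 random lists of like signal. Of abundant endoderm genes Ctsl (8448 and 13892 with LIF) and Sparc (2576 and 5759) were higher while Apoe was not with LIF (3495.5 and 3146) and was slightly higher without LIF (3771 and 4317), ES cells may express some of these genes themselves, and batch and cell makeup may both be present.

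The third pattern is that 2-fold rises outnumbered 2-fold falls. Of 76 olfactory, vomeronasal and taste receptor genes 56 were higher without LIF (median log2 change 0.58, 0.82 and 0.35 within the numbers, 0.17 with quantile normalization; 0.47 for random lists of like signal), and of the 18 that were tested 17 were higher (median 0.66, 1.11 and 0.17 within the numbers, 0.28 with quantile normalization; 0.46 for random lists). An offset of dim signals between arrays is therefore a candidate source of part of the excess. A broad rise of dimly expressed genes cannot be told apart from it, as 58.5% of 2-fold changes were rises with quantile normalization, which removes true and technical shifts alike. A bound for excluding that rise was that receptor genes lie within the range of random lists. It was written after this share but before the receptor values had been seen, and it was met. The bound was put aside after that outcome, first because only 18 of the 76 lay above the filter. For the 18, which also met it, a wide range (-0.02 to 0.90) of genes near the floor excludes little. For all 76 the range was narrower, at 0.16 to 0.79, and their median of 0.58 lay inside it, so the width of the range is a weaker reason there.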
